A study of Mus musculus with 12 samples.

How the data were processed

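Total RNA of the olfactory mucosa, the tissue that holds the olfactory sensory neurons, had been sequenced after removal of ribosomal RNA with a stranded library kit, per the labels' protocols. The 12 samples came from male mice of a mixed 129S6;C57BL/6J background at postnatal day 30, with 6 wildtype animals and 6 animals carrying the eB deletion, which removes 1,155 bp on chromosome 7 (102,847,692 to 102,848,846). The build of this interval was not given beside it in the sources used here. It was read as GRCm38, since the submitters' processing notes name GRCm38.p6, STAR 2.6.0 and DESeq2. The tool that counted reads per gene, the gene annotation and the strand setting of the counting are not given in the sources used here.

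The deposited table holds 1 row per gene (44,930 genes) and 1 column per animal, all 12 of which were matched to an animal by its label. The deposited values are a signal per gene, namely normalized counts: gene read counts that the authors divided by 1 size factor per sample, as the values themselves show. Within each column, 100% of the nonzero values were whole multiples of the smallest value (relative tolerance 0.001), so that whole reads per gene were recovered for every library. The table also holds the authors' own comparison. Its log2 fold change and standard error in the authors' deposited table are shrunken towards 0 and positive where wildtype is higher. Its score is the test statistic, which in the authors' deposited table equals the log2 fold change divided by its standard error. Its p-value and adjusted p-value are given as the authors deposited them, and the latter is blank for genes without one.

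The design fixed before the data were examined assumed raw counts and named edgeR's quasi-likelihood test. Because the file held normalized values instead, the test that the same design named for that case was used. This was limma-trend (limma 3.58.1, R 4.3.3) on log2(value + 1), with genes kept at a value of at least 10 in 6 or more samples (19,100 genes), no covariates, and Benjamini-Hochberg adjustment with a threshold of 0.05. Fold changes are therefore on the log2(value + 1) scale, which understates the change of low genes, and are given as deletion minus wildtype with their standard error. The quasi-likelihood test of edgeR 4.0.16 on the recovered reads, run as an alternative chosen after seeing the data, called 0 genes. DESeq2 1.42.0 on the recovered reads called 9 genes. Tested on simulated data drawn for the comparison of eB deletion with wildtype, over 19,100 genes with the means, dispersions and library sizes of the real data and 50 genes changed at each fold, the limma procedure recovered 8% of genes changed 1.2-fold, 60% of those changed 1.5-fold, 90% at 2-fold and 100% at 3-fold, with 5 false calls among 134. The simulated genes varied independently of each other, which real receptor genes do not. On the same simulated reads edgeR's test called 7 of the 50 genes at 1.2-fold, 30 at 1.5-fold, 48 at 2-fold and 50 at 3-fold, with 8 false calls among 143.

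Gene positions, types and exon lengths came from GENCODE M21, which is on the same build, matched by gene identifier without its version. Of the genes, 44,840 matched and 90 did not. Odorant receptor genes are those whose symbol starts with Olfr (1,380 genes). Class I genes are those among them between 102 and 106 Mb of chromosome 7 (151 genes, of which 27 are pseudogenes), and all others are class II (1,229 genes). Gene sets were tested with camera (preset correlation 0.01, and again with an estimated correlation) and with fry from limma. The lists of cell type markers and pathways were fixed before the data were examined, and 23 of them form the family over which set p-values were adjusted. Single values per animal, such as the class I share of receptor reads, were compared with an exact two-sided permutation test over all 924 assignments of animals to groups. Correlations across genes used permutation tests with 100,000 resamples. Intervals of single shares are 95% Wilson intervals from scipy 1.17.1, and they cover counting error only. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used for reading and plotting.

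The genes named were chosen by a rule fixed before the data were examined. Since fewer than 8 genes passed, it gives the 5 of smallest p in each direction as values, the 3 tested receptor genes nearest to the deletion on each side, and up to 4 members of each list described, those of highest mean where no member passed. The value of 1 gene that this rule gives is not reported here. Libraries of a group were compared for duplicates. The lowest chi-square per degree of freedom between 2 libraries of the same group was 14.5, so no library stood under 2 labels of its group. Alternatives covered size factors, filters, pseudocounts of 0.5 and 5, other tests, covariates, list boundaries, distance windows and leaving out each animal in turn, with the genes tested kept as with all 12 animals. Alternatives that had been laid out with TMM as the starting point were adapted: edgeR was run with DESeq2 size factors, which the deposited values already carry, and class II scaling was applied to the deposited values. The rescaling by TMM and the 2 exclusions of libraries by their reads on Gm10800, with the comparison within the excluded libraries, were chosen after seeing the data. No gene lies in the deleted interval, so that no gene's level tests the labels. P-values of single genes, of fry and of values per animal measure the spread between animals. Those of correlations across genes measure the spread between genes. Camera compares the genes of a list with other genes, and its preset correlation allows for little shared variation of a list between animals.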

Results

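The expression of all genes was measured by RNA sequencing in the olfactory mucosa of 6 wildtype mice and 6 mice that lack eB, an enhancer of class I odorant receptor genes. Odorant receptors are the G protein-coupled receptors of olfactory sensory neurons. Class I receptors, which resemble those of fish, lie in 1 cluster on chromosome 7, whereas class II receptors are spread over many chromosomes. The deleted interval (chromosome 7, 102,847,692 to 102,848,846, GRCm38) overlapped no annotated gene and lay between the receptor pseudogene Olfr565-ps1 and Olfr566, within the class I cluster, whose annotated genes extended from 102,476,579 to 105,369,355. The libraries held between 13,152,662 (wildtype 2) and 23,059,835 (eB deletion 3) reads on genes. Odorant receptor genes took 0.75% ± 0.06 (SD, n = 6) of reads in wildtype and 0.76% ± 0.04 (SD, n = 6) in deletion animals. Between 103,840 and 163,236 reads per library stood behind the receptor shares below. In wildtype 2, 11.02% of reads fell on the predicted gene Gm10800. The same gene took 2.38% of reads in eB deletion 4, 0.55% in eB deletion 1 and 0.33% in wildtype 5.

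The first comparison asked which genes differ between the genotypes. Of 19,100 genes tested, 0 passed an adjusted p of 0.05 in limma-trend, while 1,078 had an unadjusted p under 0.05, 540 of them higher and 538 lower in the deletion. On the recovered reads, edgeR's quasi-likelihood test called 0 genes and DESeq2 called 9. The authors' deposited table lists 8 genes past an adjusted p of 0.05, with RP24-247B20.1, Olfr1018, Mtmr10, Slc2a3, Olfr711 and Kcnj5 higher and Olfr577 and Olfr420 lower in the deletion. All 8 were among the 9 that DESeq2 called here, and the other was RP23-403A4.1. The genes of smallest p are given as values. The long noncoding RNA RP24-247B20.1 on chromosome 9 had 42.1 ± 18.0 normalized counts in wildtype and 128 ± 45.8 in deletion animals (SD, n = 6 each), a log2 fold change of 1.62 ± 0.28 (SE). The class II receptor genes Olfr1018 (0.78 ± 0.14) and Olfr711 (0.51 ± 0.10), the glucose transporter gene Slc2a3 (0.36 ± 0.07) and the stathmin gene Stmn4 (0.44 ± 0.10) had higher log2 values in all 6 deletion animals than the wildtype mean. Lower in all 6 were the class I receptor gene Olfr577 (-0.65 ± 0.11), the class II receptor gene Olfr420 (-0.70 ± 0.13), the histone gene Hist1h2ab (-0.81 ± 0.17), the neuronal adhesion gene Cntnap2 (-0.52 ± 0.11) and the interleukin receptor gene Il1r1 (-0.53 ± 0.11). The adjusted p of these 10 genes in limma-trend lay between 0.208 and 0.557. Without wildtype 6 the count became 1 gene, Olfr1018 (limma adjusted p = 0.040).

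The second comparison concerned the class I receptor genes themselves. Of 120 class I genes tested, 111 had lower and 9 higher values in the deletion, with a median log2 fold change of -0.24, or -15.5%. No single class I gene passed over all genes in limma-trend, whereas 27 had an unadjusted p under 0.05, all of them lower (12 to 48 when 1 animal was left out), and DESeq2 called 1. Adjusted over the list alone, 1 class I gene passed, Olfr577, with 97.6 ± 12.5 normalized counts in wildtype and 61.6 ± 5.57 in deletion animals (SD, n = 6 each; limma adjusted p over the list = 0.0029). Olfr577 overlaps Olfr576, and reads of receptor paralogs and overlapping genes could be split by the counting, so that single receptor values are uncertain. The lower values were found at every level of expression, with 25 of 30 class I genes lower in the lowest quartile of mean level and 30 of 30 in the highest. As a set, class I genes were lower relative to all other genes (camera p = 4.3e-24 with the preset correlation, and p = 0.045 with an estimated correlation of 0.35). Against no change, rather than against other genes, the mean log2 value of class I genes differed by -0.25 ± 0.11 (SE; exact permutation p = 0.045, adjusted 0.136 over 9 values; fry p = 0.047). The call was lost with an estimated correlation in 8 of 12 fits that left out 1 animal (wildtype 1, 2, 4 or 5, or eB deletion 3, 4, 5 or 6), with p from 0.017 to 0.110 over the 12 fits. The camera test with an estimated correlation gave p = 0.12 without wildtype 2 and eB deletion 4 and p = 0.081 without all 4 libraries with over 0.1% of reads on Gm10800. Without these 4 libraries, 109 class I genes were lower, and 0 passed over the list alone. Without eB deletion 1, 11 passed over the list alone.

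**Figure D1:**
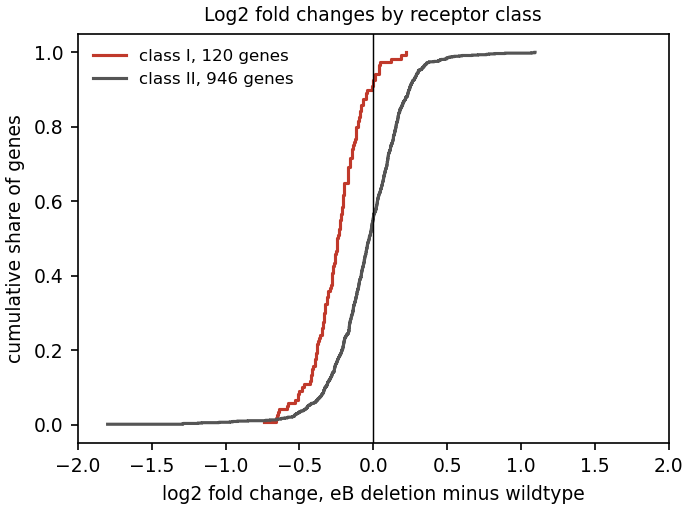
Cumulative share of genes (y axis) against log2 fold change, eB deletion minus wildtype (x axis), for 120 class I and 946 class II odorant receptor genes. The class I curve lies to the left, with a median of -0.24 against -0.03 for class II.

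Per animal, class I genes took 9.91% ± 0.37 of all odorant receptor reads in wildtype and 8.52% ± 0.87 in deletion animals (SD, n = 6 each). The difference was -1.39 percentage points ± 0.39 (SE), 13.99% of the wildtype share (exact permutation p = 0.0065, two-sided). It was 1 of 9 values compared per animal, over which its Benjamini-Hochberg adjusted exact p was 0.058. Of the 6 deletion animals, 5 lay below the lowest wildtype animal. The exception was eB deletion 1 at 9.72% (95% Wilson interval 9.55 to 9.88), and the lowest was eB deletion 5 at 7.07% (6.93 to 7.21). Among the 8 libraries with at most 0.1% of reads on Gm10800, 4 per group, the difference was -1.81 points (exact permutation p = 0.029, the smallest p that 70 assignments allow). Among the 4 others, 2 per group, it was -0.54 points ± 0.68 (SE; exact permutation p = 0.667 over 6 assignments). As a share of all reads, class I genes took 0.074% ± 0.004 in wildtype and 0.065% ± 0.010 in deletion animals (SD, n = 6 each; exact permutation p = 0.063).

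**Figure D2:**
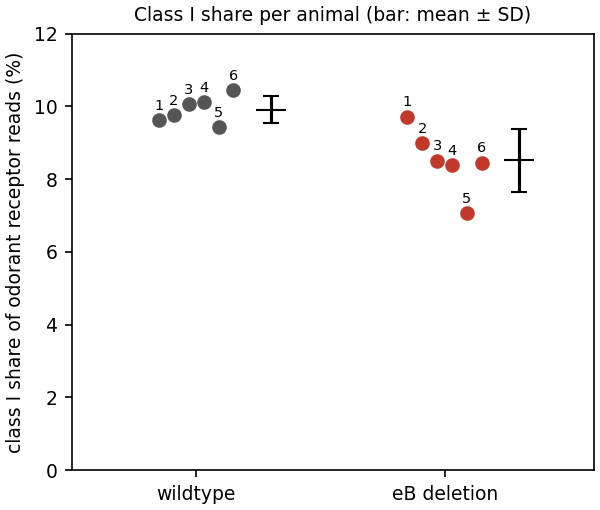
Share of odorant receptor reads that fell on class I genes (y axis, percent) in each animal, with the animal's number beside its point and the mean ± SD of 6 animals as a bar. In the deletion group, 5 of 6 animals lie below the lowest wildtype animal.

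Class II receptor genes served as the internal comparison. Of 946 tested, 526 were lower and 420 higher, with a median log2 fold change of -0.03 that turned to 0.01 without wildtype 2 and to 0.01 without the 4 libraries with over 0.1% of reads on Gm10800. No class II gene passed over all genes in limma-trend, 103 had an unadjusted p under 0.05, and DESeq2 called 3. Adjusted over the list alone, 3 passed in limma, Olfr1018 and Olfr711 with higher and Olfr420 with lower values. This count was 0 without any of wildtype 1, 2 or 3 or eB deletion 2, 3, 4 or 5. As a set they did not pass camera with either correlation (p = 0.15, and p = 0.74 with an estimated correlation), though the preset correlation gave a call in 4 of 12 fits that left out 1 animal (lowest p = 9.1e-05). The difference between the classes was compared directly: mean log2 values of class I minus class II genes were lower in deletion animals by -0.21 ± 0.08 (SE; exact permutation p = 0.024, adjusted 0.107 over 9 values). The trace amine receptors, the other family of olfactory receptors, had 11 of 12 tested members lower, with a median of -0.20 (-0.34 to -0.09 when 1 animal was left out). Taar9 was at -0.38 ± 0.18 (SE), Taar7b at -0.23 ± 0.21, Taar7d at -0.04 ± 0.14 and Taar6 at -0.01 ± 0.14. The list passed camera (adjusted p = 0.0077), but not with an estimated correlation (adjusted p = 0.71) and not in 5 of 12 fits that left out 1 animal. The mean log2 value of class I minus trace amine receptors differed between deletion and wildtype by -0.01 ± 0.16 (SE; exact permutation p = 0.96).

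The next comparison asked whether the change followed the distance from eB. Among 25 tested receptor genes within 250 kb, 24 were lower, with a median of -0.28 (camera p = 0.026 with an estimated correlation), and among the 95 class I genes farther away 87 were lower, with a median of -0.23 (p = 0.056 with an estimated correlation). Within 250 kb, 0 genes passed over all genes in limma, 6 had an unadjusted p under 0.05, DESeq2 called 1, and 1 passed adjusted over the list alone, Olfr577, which lies 122 kb away. The 3 nearest tested receptor genes at higher coordinates were Olfr566 at 6.49 kb (-0.42 ± 0.34, SE), Olfr568 at 28.3 kb (-0.12 ± 0.15) and Olfr569 at 34.9 kb (-0.17 ± 0.11). At lower coordinates they were Olfr564 at 43.3 kb (-0.38 ± 0.44), Olfr561 at 70.8 kb (-0.34 ± 0.14) and Olfr78 at 88.2 kb (-0.17 ± 0.10). None of these passed over all genes (limma adjusted p from 0.850 to 0.961). Across the 120 class I genes, at 6.49 to 2519 kb, log2 fold change did not follow log10 distance (Spearman rho = -0.04, permutation p = 0.70; Pearson r = 0.003, permutation p = 0.97). Genes are not independent replicates. Without the 2 genes farthest from the median distance, r was -0.01. Nonreceptor genes within and around the cluster, 38 of them tested, had a median of 0.02 and 0 past the threshold (camera adjusted p = 0.56). Among them, Cnga4 was at 0.02 ± 0.08, Apbb1 at 0.02 ± 0.05 and Nup98 at 0.14 ± 0.07. Nup98 lies at lower coordinates than every class I gene, and Cnga4 and Apbb1 at higher coordinates. Apart from the beta-globin genes, nonreceptor genes lying between class I genes were not tested as a list of their own. Of the beta-globin genes, Hbb-bs was at -0.11 ± 0.28 and Hbb-bt at -0.06 ± 0.31 (camera adjusted p = 0.73 for this list).

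**Figure D3:**
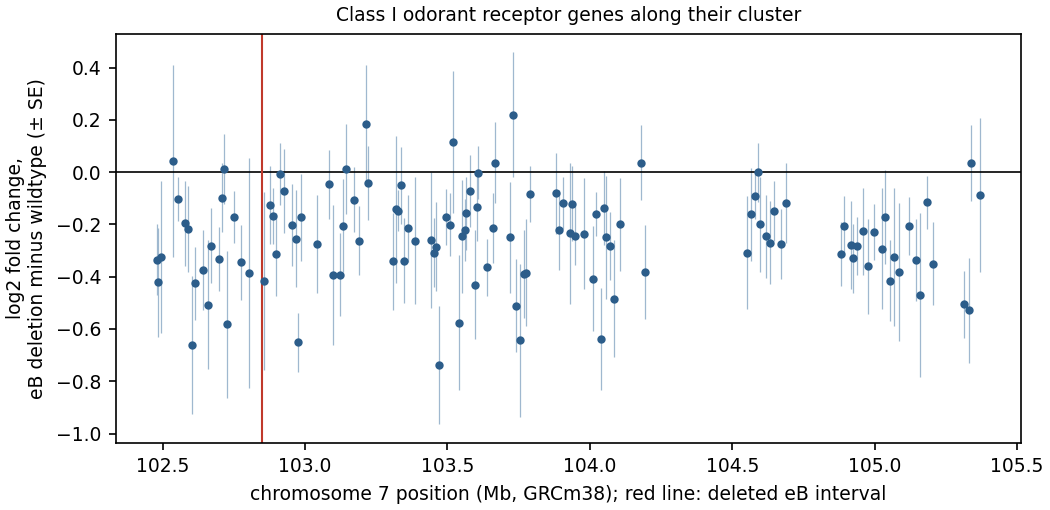
Log2 fold change, eB deletion minus wildtype (y axis, ± SE), of each of 120 tested class I genes at its position on chromosome 7 (x axis, Mb, GRCm38), with the deleted interval as a red line. Of the genes, 111 lie below 0, on both sides of the deletion.

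Of the 23 lists of cell types and pathways, 4 passed camera with the preset correlation and 1 with an estimated correlation. The list fixed beforehand under the name dissection stress holds immediate early genes, which respond within minutes to stimulation, and the heat shock genes Hspa1a and Hspa1b. It rose as a set: all 12 members were higher, with a median of 0.34 (camera adjusted p = 2.1e-13, and adjusted p = 0.025 with an estimated correlation), and 9 passed adjusted over the list alone, against 0 over all genes. The 3 that did not pass were Fosb, Hspa1a and Hspa1b, named after their values were seen. The mean of the list was higher by 0.43 ± 0.11 (SE; exact permutation p = 0.0022, the smallest p that this test allows, adjusted 0.050 over 23 lists). Jun was at 0.15 ± 0.04 (SE), Dusp1 at 0.32 ± 0.11, Btg2 at 0.31 ± 0.10 and Ier2 at 0.22 ± 0.08. With an estimated correlation the adjusted p was 0.050 without wildtype 5, 0.069 without wildtype 6 and 0.099 without the 4 libraries with over 0.1% of reads on Gm10800, where all 12 members were again higher. With a replicate block it was 0.235.

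**Figure D4:**
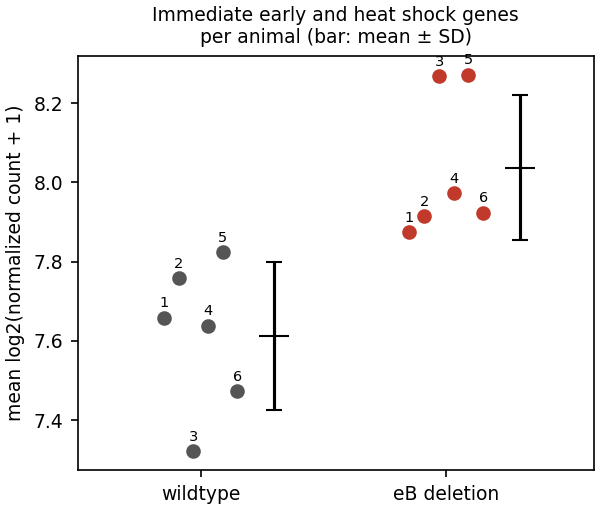
Mean log2(normalized count + 1) of 12 immediate early and heat shock genes (y axis) in each animal, with the animal's number beside its point and the mean ± SD of 6 animals as a bar. The list mean is higher by 0.43 in the deletion group.

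Interferon response genes had 13 of 15 members lower and a median of -0.22 (camera adjusted p = 0.00099), a call lost with an estimated correlation (adjusted p = 0.092) and without the 4 libraries with over 0.1% of reads on Gm10800 (adjusted p = 0.053). Ifi27l2a was at -0.49 ± 0.16 (SE), Ifit1 at -0.07 ± 0.11 and Ifit2 at 0.03 ± 0.06. Neuronal progenitor markers had a median of -0.09 (camera adjusted p = 0.046, and adjusted p = 0.71 with an estimated correlation), with Mki67 at -0.09 ± 0.11, Top2a at -0.10 ± 0.10 and Sox11 at 0.00 ± 0.06. The call was lost in 8 of 12 fits that left out 1 animal, where the median ran from -0.15 to -0.06. Without the 2 libraries with over 1% of reads on Gm10800 the median was -0.19 (camera adjusted p = 8.7e-07, and adjusted p = 0.019 with an estimated correlation), and without the 4 with over 0.1% it was -0.21 (camera adjusted p = 0.00012, and adjusted p = 0.099 with an estimated correlation). The preset-correlation count of lists was 7 without wildtype 3, and 2 without wildtype 4 or without eB deletion 6.

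The other lists did not pass camera (adjusted p from 0.051 to 0.91). Mature sensory neuron markers had a median of 0.03, with the olfactory marker protein gene Omp at -0.03 ± 0.09 (SE), the G protein gene Gnal at 0.06 ± 0.08 and Stoml3 at 0.07 ± 0.09, and immature neuron markers a median of -0.02, with Tubb3 at -0.12 ± 0.05, Dpysl3 at 0.11 ± 0.08 and Stmn1 at -0.01 ± 0.05. Sustentacular (supporting) cells had a median of 0.06, with Cyp2a5 at 0.02 ± 0.13 and Cyp2g1 at -0.05 ± 0.09. Horizontal basal cells had a median of -0.05, with Krt5 at -0.05 ± 0.14 and Krt14 at -0.05 ± 0.11, and Bowman's glands -0.07, with Bpifb3 at 0.18 ± 0.10 and Obp1a at -0.65 ± 0.63. The median was -0.03 for ciliated respiratory cells, 0.04 for microvillar cells, -0.06 for ensheathing glia, -0.10 for red blood cells, -0.11 for immune cells, -0.06 for vomeronasal neurons, and -0.07 for the nasal skeleton and muscle (mean 0.02, of the opposite sign). Adjusted over the list alone, 1 mature neuron gene passed with higher values (Pde4a; limma adjusted p over the list = 0.042) and 1 microvillar gene with lower values (Moxd2; limma adjusted p over the list = 0.040), both named after their values were seen. Regulators of receptor choice had a median of 0.02, with Rtp1 at 0.09 ± 0.07 and Ebf2 at 0.05 ± 0.06, and genes of the unfolded protein response a median of 0.01, with the chaperone gene Hspa5 at 0.01 ± 0.07. Genes that follow neuronal activity had a median of 0.02. In this list S100a5 was at -0.35 ± 0.13 and Kirrel2 at -0.23 ± 0.22, and its fry test for change in either direction passed (adjusted p = 0.0088). The 4 members that passed adjusted over the list alone were all higher: Fos, Egr1, Junb and Bhlhe41, named after their values were seen, of which the first 3 are also immediate early genes of the list above. Genes of the dorsal zone, 3 of 7 lower and 4 higher, had a median of 0.03 and a mean of -0.06, of opposite sign. Among them, the dorsal neuron gene Nqo1 was at -0.35 ± 0.14, Acsm4 at -0.08 ± 0.09 and Robo2 at 0.03 ± 0.06. Genes of the ventral zones had a median of 0.04, with Nrp2 at 0.15 ± 0.06 and Nfib at 0.14 ± 0.06.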

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

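All tests on the 3 patterns in this part were chosen after the patterns were seen. Only for the ratio of X to autosomes was the prediction written down before the value was known. Within each group of 6, a value was picked out where its gap to the nearest other exceeded the critical value of Dixon's ratio test for 6 values. This met 11 of 184 groups of values, and chance alone gives about 1 in 20, or 9.2.

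The first pattern is in the libraries. In wildtype 2, 42505 genes had a read, against 29451 to 32060 in the other wildtype libraries, and Gm10800 took 11.02% of reads, against at most 0.33%. In eB deletion 4, Gm10800 took 2.38%, against at most 0.55% in the other deletion libraries. Deeper sequencing is argued against, since the deeper of both libraries held 15.8 M reads and the median library 18.3 M. Genomic DNA in the library is a candidate explanation: over 426 genes on X and 7323 on autosomes without a read in the 8 other libraries, reads per kb of exon on X were 0.66 times those on autosomes in wildtype 2 (95% bootstrap interval 0.61 to 0.72) and 0.65 times in eB deletion 4 (0.58 to 0.72), inside the range of 0.3 to 0.7 set beforehand, though above the 0.5 of 1 X to 2 autosomes in males. Of the 2 libraries with fewer reads on Gm10800, eB deletion 1 was at 0.46 and wildtype 5 at 0.81 (0.61 to 1.02), which leaves genomic DNA in wildtype 5 open. No biological explanation was tested.

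The second pattern is the lower class I share of receptor reads. A single deviating animal is argued against, as the exact permutation p was at most 0.011 without any 1 animal. Genomic DNA is argued against too: without the 4 libraries with over 0.1% of reads on Gm10800 the difference was -1.81 points. Less dorsal epithelium in the deletion dissections stays open. Class I receptors are dorsal, and their change could not be told apart from that of the trace amine receptors, also dorsal. The mean log2 value of class I minus trace amine receptors differed between deletion and wildtype by -0.0097 ± 0.156 (SE). Other dorsal genes were mixed. Of the 7 tested genes of the dorsal list, 3 were lower and 4 higher. The list had a median of 0.03 and a mean of -0.06 ± 0.04 (SE; exact permutation p = 0.19). Nqo1 was at -0.35 ± 0.14, Acsm4 at -0.08 ± 0.09 and Robo2 at 0.03 ± 0.06. Msx1, named after its values were seen, was below the wildtype mean in all 6 deletion animals. The mean log2 value differed by -0.24 ± 0.18 (SE) for trace amine receptors and by -0.25 ± 0.11 for class I genes, about as much, as less dorsal epithelium would give. The trace amine receptors varied much between animals, and their own difference did not pass (exact permutation p = 0.20). By the trace amine receptors, less dorsal epithelium and the deletion of eB itself, which the design names, therefore cannot be told apart here. The mean of the dorsal list fell less than that of the class I genes, a difference that was not tested.

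The third pattern is the higher level of immediate early genes. Another cell mixture is argued against for most cell types listed, since the highest median of a cell type list, sustentacular cells, was 0.057 against 0.34. For red blood cells (mean -0.19 ± 0.31, SE) and the nasal skeleton and muscle (mean 0.02 ± 0.22) this cannot be decided. Their lists varied too much between animals, with 0.34 inside 2 standard errors of the mean. More odor-driven activity of sensory neurons stays open: the activity-dependent genes S100a5 and Kirrel2 were not higher (-0.29 ± 0.19, SE; exact permutation p = 0.16), which cannot be told apart from no change. The bound of this test was widened from 1 to 2 standard errors after its value was seen. The value lay between these bounds, so the bound of 1 standard error would have argued against this explanation. Of the 2 genes, S100a5 was below the wildtype mean in all 6 deletion animals (-0.35 ± 0.13) and Kirrel2 in 4 (-0.23 ± 0.22). Handling of the tissue before lysis was not tested, since the labels give no times, and neither was an effect of genotype.

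Other values that stood apart are given without explanation. The mean log2 value of the progenitor list was 8.80 in eB deletion 4, against 8.46 to 8.51. That of nonreceptor genes within and around the cluster was 7.65 in eB deletion 5, against 7.78 to 7.82. In eB deletion 2, Il1r1 was at 92.3 normalized counts and Stoml3 at 35194. In wildtype 1, Acsm4 was at 14656.5 and Ier2 at 561, and in wildtype 4 Ifit1 was at 550.3. Hspa5 was at 13141 in eB deletion 5.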

How the results depend on the processing

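Settings for the 4 libraries with Gm10800 reads, TMM and edgeR's quasi-likelihood test, and each refit of the estimated-correlation p, were chosen after seeing the data. Across all values and settings, 829 stayed the same. These are tests that kept direction and side of the threshold, passed or not, and counts that were equal or within 1.5 times. Of the tests, 40 lost the call, 15 gained one and 3 turned direction. Of the counts, 48 differed by over 1.5 times or moved from or to 0. The class I median stayed below 0 in every setting, from -0.16 to -0.30 without 1 animal. With DESeq2, 9 genes, 1 class I gene, 3 class II genes and 1 receptor gene within 250 kb passed, against 0 of each in limma. The cause was not tested. Without 1 animal the counts ranged from 0 to 1 for all genes and for class II genes, and stayed at 0 for class I genes and for those near the deletion. The lists past camera were 4, and 1 with an estimated correlation, 9 without a filter on low values, where more genes enter, and 2 to 7 without 1 animal.

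With an estimated correlation, the class I set lost its call while its median was -0.23 with edgeR on DESeq2 size factors (p = 0.058), -0.24 with limma-voom (p = 0.062), -0.23 beyond 250 kb (p = 0.056), -0.23 with edgeR and TMM (p = 0.062), -0.25 with values rescaled by TMM (p = 0.062), -0.20 without the 2 libraries with over 1% of reads on Gm10800 (p = 0.12) and -0.28 without the 4 libraries with over 0.1% (p = 0.081). The last 2 hold fewer samples. For the others the cause was not tested. Without 1 animal the median ranged from -0.30 to -0.16. The class I share differed by -1.63 to -1.10 points without 1 animal. As a percentage of all reads the difference was -0.0092 (exact permutation p = 0.063). The correlation with distance ranged from -0.095 to 0.039 without 1 animal, and among genes beyond 250 kb was -0.170 (permutation p = 0.098). The class II median ranged from -0.072 to 0.014 without 1 animal, and was 0.012 without the 4 libraries.

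No pairing of animals by replicate number was seen: deviations of same-numbered animals correlated at -0.12 to 0.16, and 1 of 6 wildtype animals correlated best with its own number. Wildtype 2 correlated best with eB deletion 4, the 2 libraries with over 1% of reads on Gm10800. Such library differences enter these correlations, so this check cannot exclude pairing. With a replicate block, 0 genes passed, and the class I share gave a difference of -1.39 points with a sign-flip p of 0.063. Adjusted over the list alone, class II calls went from 3 to 1 with the block, and the immediate early list lost its call with an estimated correlation (adjusted p = 0.235). Power for single genes near the class I median was low at this depth, spread and group size, as 8% of simulated genes changed 1.2-fold were recovered. Those genes were drawn from all genes tested. In 20 simulations that shifted the 120 class I genes by -0.25 in log2, limma called a mean of 0 of them. The count of 0 class I genes in limma therefore does not argue against a change of this size.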

Other observations

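All tests here except those of counts of genes and lists were chosen after the results were seen. Odorant receptor genes vary together between animals. When the 12 samples were divided into groups of 6 in 100 of the 462 possible ways, the real one included, camera with its preset correlation gave the class I genes p under 0.05 in 77 splits and with an estimated correlation in 5. The preset p is therefore no measure of the genotype for this list. The class I median lay as far from 0 as the real -0.24 in 3 of 100 splits (highest other 0.34), a share under 0.05. This median is 1 of several values tried on these genes, without adjustment, so its share does not exclude chance. At least the real 111 class I genes in 1 direction were found in 6 of 100 splits. The mean log2 value of the class I genes had an exact permutation p of 0.045, which became 0.136 adjusted over the 9 values compared per animal.

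The splits decide nothing for single genes. The real split called 0 genes, 0 class I genes, 0 class II genes and 0 receptor genes near the deletion, so that 100 of 100 splits had to call as many, and the highest other counts were 1 for all genes, 0 for class I, 1 for class II and 0 near the deletion. At an unadjusted p under 0.05, 29 of 100 splits gave as many genes as the real 1078, and the highest other count was 2091, which points to a structure of the samples. For the lists, 46 of 100 splits called as many as the real 4, with up to 14 in another split, so chance cannot be excluded for that count.

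Class I genes on the lower-coordinate side of the deletion had a median log2 fold change of -0.33 (17 of 19 lower) and those on the other side -0.23 (94 of 101 lower). This difference was not tested.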
